A study of Homo sapiens with 4 samples.

How the data were processed

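Total RNA of the human glioma cell line U251-MG was sequenced in 4 libraries, 2 from cells infected with a lentiviral vector carrying the COL8A1 coding sequence and 2 from cells infected with the same kind of vector as a negative control (NC). The groups and the replicate numbers were taken from the sample titles. The labels do not say whether the 2 libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

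The deposited values were raw read counts per gene, 1 column per library, with no normalization. Trim Galore 0.6.9, HISAT2 2.2.1, featureCounts (listed as version 0.3) and the human build hg38 are named in the submitters' processing notes. Their parameters, the strand setting of the counting and the release of the gene annotation are not given in the sources used here. Without a known strand setting, the reads of overlapping genes on opposite strands cannot be told apart. Reads of near-identical genes, such as HSPA1A and HSPA1B, the HLA genes and ribosomal protein genes with processed copies, may be shared between them, and their values are uncertain.

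The table held 61806 genes with Ensembl identifiers, and 1 further line was a protein domain record with 0 reads that was left out. Symbols were found for 41389 of the genes, and 58254 were placed with the GENCODE release 29 annotation, whose assembly is the same build as hg38 but whose gene models may differ from those used for counting. The total count per library ran from 27923796 to 33576228. PCR copies of a molecule were counted as separate reads.

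Differential expression was tested in R 4.3.3 with edgeR 4.0.16: genes kept by filterByExpr with the group as design, TMM scaling factors, and the quasi-likelihood fit and F-test with the group as the only term. The filter left 17030 genes, the fit had 2 residual degrees of freedom, and its prior degrees of freedom were estimated at 2.64. Adjusted p-values follow Benjamini and Hochberg over all genes tested, with a threshold of 0.05. Standard errors (SE) of log2 fold changes were computed as the absolute log2 fold change divided by the square root of the F statistic. They thus restate the edgeR test and are not a separate estimate of precision. CPM (counts scaled to library size) were computed from the deposited counts with TMM-scaled library sizes and are given as mean ± SD of the 2 libraries of a group.

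Before the data were examined, 36 gene lists were fixed. They covered collagens and their processing, other matrix genes, adhesion, mesenchymal and glioma subtype genes, growth and stress signalling, the cell cycle, metabolism, interferon and inflammation, RNA and protein handling, and markers of other cell types. Of the 1067 symbols in them, 1066 were found in the table. COL8A1 itself was left out of the collagen list. Each list was tested against the other genes with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01 between genes, adjusted over the 36 lists, and again with an estimated correlation and with fry.

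The genes named were set by a rule fixed at the same time. They are COL8A1, the 10 largest increases and decreases past the threshold with a mean of at least 5 CPM and no overlap between the groups, and the 5 smallest p-values. To these were added the 4 members with the smallest p-values of each list past the threshold and of 5 further lists (collagens, collagen processing, mesenchymal transition, PI3K and AKT signalling, G2 and M phase), the other collagen VIII chain COL8A2, and the collagen receptors ITGA1, ITGA2, ITGB1, DDR1 and DDR2. Any other gene is said to have been chosen after its values were seen. For 1 gene that the rule names, the result is not reported here.

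The alternatives were other scaling factors, library size alone, COL8A1 left out before scaling, no low-count filter or a filter of 1 CPM in 2 libraries, the replicate number as a block, DESeq2 1.42.0, limma-voom, fold thresholds, and each library left out in turn. Added after seeing the data were robust dispersion shrinkage, counts summed over overlapping genes, lists without genes that differed over 2-fold within a group, and lists after removing a trend with transcript length. Leaving out genes by their difference within a group removes spread that the test measures and keeps genes that part the groups. Calls gained in this way may come from the filter. The fits were tested on simulated counts drawn with the means, library sizes and fitted dispersions of this comparison, for the 16544 simulated genes that passed the filter. edgeR recovered 56.7% of genes changed 2-fold, 97% of those changed 4-fold and 100% of those changed 16-fold, with 32 false calls. DESeq2 recovered 82.1%, 97% and 100% of the same genes, with 61 false calls. With a dispersion of 0.01 in all genes, below the fitted common dispersion of 0.0508, both recovered 100% at each fold over 16655 genes, with 10 false calls in edgeR and 9 in DESeq2. A simulated list shifted 1.3-fold was called, and 0 of the other 35 lists were. The counts of each gene were drawn independently, so this check cannot show calls that correlation between genes would cause. The simulated shift was also larger than the median shift of every list called in the real data.

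A gene was said to have separate count levels when it had a mean of at least 300 counts, a gap of more than 1 on the log2 CPM scale between libraries, and libraries on either side of the gap within 0.5 of each other. As a comparison, negative binomial counts were drawn at each gene's mean with the edgeR dispersions; genes outside the filter took the common dispersion. The share of a gene's longest transcript held by its longest exon was taken from the GENCODE release 29 annotation. Figures were drawn with matplotlib 3.10.9.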

Results

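Transcript levels of U251-MG cells, an established human glioblastoma line grown in culture, were compared between 2 libraries from cells carrying a COL8A1 overexpression vector and 2 libraries from cells carrying the control vector (NC). The total counts were 30895414 and 33576228 in NC replicates 1 and 2, and 31605164 and 27923796 in COL8A1 replicates 1 and 2. Between 22764 and 23546 genes had at least 1 count. TMM scaling factors ran from 0.993 to 1.007. The 13 protein-coding mitochondrial genes took 4.03% to 4.32% of the counts.

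COL8A1 (ENSG00000144810) encodes a chain of collagen VIII, a short-chain network-forming collagen, and lies on chromosome 3 from 99638475 to 99799226 on the plus strand (GENCODE release 29). It had 77 and 82 counts in the NC libraries and 4290 and 2259 in the COL8A1 libraries. Its level was 2.47 ± 0.055 CPM in NC and 108 ± 37.9 CPM in COL8A1 cells (SD, n = 2 each), a 43.7-fold difference in the direction of the labels. The log2 fold change was 5.45 (SE 0.315), with an unadjusted edgeR p of 2.16e-05 and an adjusted p of 0.0681, which missed the threshold. In DESeq2 the adjusted p was 6.25e-72, in edgeR without a low-count filter it was 0.00737, and in edgeR without COL8A1 replicate 2 it was 0.0313. The other chain of the collagen, COL8A2, had 0, 13, 9 and 8 counts in the 4 libraries and was too low to be tested.

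The first question was which genes differed between the vectors. Of 17030 genes tested, 2 passed the edgeR threshold, both lower in COL8A1 cells. ZNF664 (ENSG00000179195; chromosome 12, 123971845 to 124015439, plus strand), which encodes a zinc finger protein, fell by 3.21 on the log2 scale (SE 0.065, edgeR adjusted p = 0.00288), from 455 ± 2.5 to 49.3 ± 1.4 CPM (SD, n = 2). RAB31 (ENSG00000168461; chromosome 18, 9708165 to 9862551, plus strand), a small GTPase of vesicle transport, fell by 2.30 (SE 0.089, edgeR adjusted p = 0.0294), from 186 ± 14.3 to 37.6 ± 1.04 CPM (n = 2). ZNF664 shares exons with 3 other counted genes on its strand, and the sum over these 4 genes was 14016, 15290, 1556 and 1465 counts in NC replicates 1 and 2 and COL8A1 replicates 1 and 2.

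Besides COL8A1, the next genes by p-value missed the edgeR threshold. ZNF672 (ENSG00000171161; chromosome 1, 248838210 to 248849517, plus strand), another zinc finger gene, was at 6.63 ± 0.70 CPM in NC and 38.5 ± 1.77 CPM in COL8A1 cells (log2 fold change 2.54, SE 0.133, edgeR adjusted p = 0.0639, n = 2). MAFG (ENSG00000197063; chromosome 17, 81918270 to 81927714, minus strand), a small Maf transcription factor, was at 81.3 ± 3.7 and 23.3 ± 1.01 CPM (log2 fold change −1.80, SE 0.096, edgeR adjusted p = 0.0639, n = 2). MAFG shares exons with 1 other counted gene on its strand, and the sum over both was 3541, 3893, 1881 and 1797 counts in NC replicates 1 and 2 and COL8A1 replicates 1 and 2, with a log2 fold change of −0.90 (edgeR adjusted p = 0.0987).

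**Figure D1:**
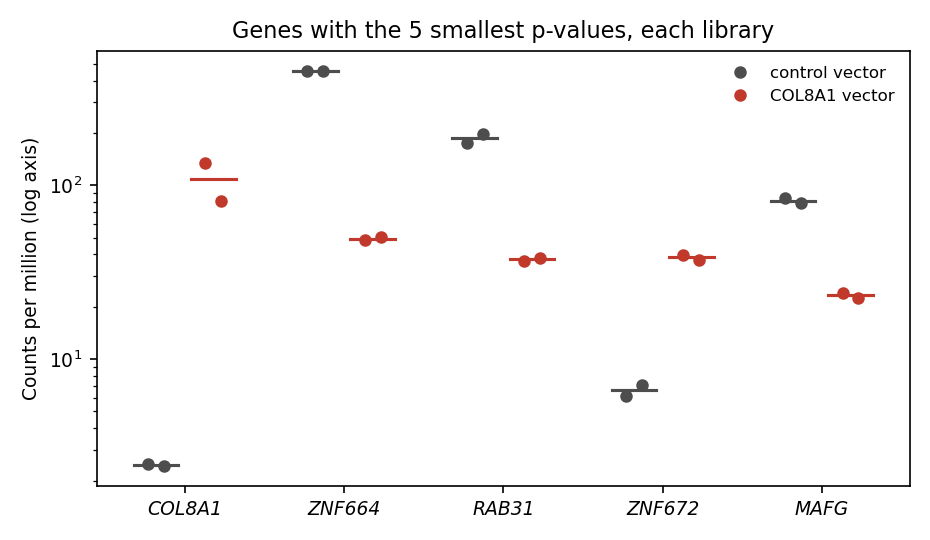
CPM (counts scaled to library size; log axis) of the 5 genes with the smallest edgeR p-values. Each point is 1 library and each line the mean of the 2 libraries of a group. COL8A1 lay at 2.47 CPM on average in the control libraries and 108 CPM in the COL8A1 libraries, and ZNF664 at 455 and 49.3 CPM.

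At an unadjusted p under 0.05, 585 genes were higher and 448 lower in COL8A1 cells, where edgeR called 0 higher and 2 lower after adjustment and DESeq2 called 103 higher and 77 lower. Leaving out COL8A1 replicate 1 gave 0 edgeR calls (ZNF664 log2 fold change −3.18, adjusted p = 0.0782), leaving out NC replicate 1 gave 1, and RAB31 missed the threshold whichever library was left out (log2 fold change −2.38 to −2.23, adjusted p 0.0757 to 0.15). The folds thus stayed near −3.21 and −2.30 while 1 group was down to 1 library, so the lost calls do not show that these changes rest on a single library.

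Some genes had 2 separate count levels among the 4 libraries. Of 10041 genes with a mean of at least 300 counts, 247 did so. Counts drawn at the same means without separate levels gave 19 with the trended edgeR dispersions, 33 with those of each gene and 68 with the common dispersion of 0.0508. In 146 of them 1 library was at the lower level, in 31 genes 1 library was at the higher level, and in 70 the libraries stood 2 against 2. JUN, chosen as an example after its values were seen, had 4128, 4574, 4687 and 271 counts in NC replicates 1 and 2 and COL8A1 replicates 1 and 2. Of the 70 genes, 22 parted the COL8A1 from the NC libraries, 23 parted the replicate numbers and 25 parted the libraries crosswise. ZNF664, RAB31, ZNF672 and MAFG were among the 22, and 13 of the 14 genes that edgeR called with robust dispersion shrinkage were too. Any well-counted gene with close replicates and a group difference above 1 on the log2 scale meets the definition, whatever the cause. This overlap therefore does not tell causes apart.

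**Figure D2:**
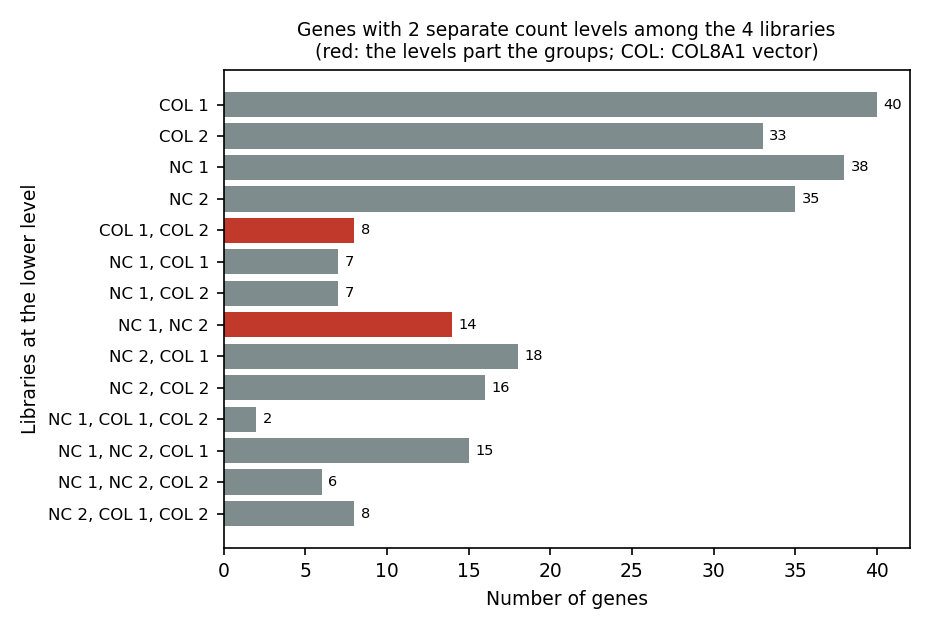
Number of genes (horizontal axis) with 2 separate count levels, by the libraries that were at the lower level (vertical axis; COL, COL8A1 vector). Red bars are the patterns that part the groups, with 8 genes lower in both COL8A1 libraries and 14 lower in both NC libraries. The largest bar is the 40 genes low in COL8A1 replicate 1 alone.

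The second question was whether groups of genes shifted together. With the preset correlation, camera called 6 of the 36 lists, 2 higher and 4 lower in COL8A1 cells. With an estimated correlation it called none of them (adjusted p = 0.845 for each of the 6), and fry called 0 lists. The estimated setting takes its p-values from the 2 residual degrees of freedom, so calls can be lost without any correlation. For astrocyte markers, with an estimated correlation of −0.052, the unadjusted camera p rose from 0.0117 to 0.116. In the 6 lists called, however, the estimated correlations all lay above the preset 0.01. They were 0.322 for ribosomal protein genes, 0.188 for interferon response genes and 0.074 for heat shock genes. For the matrix list the estimate was 0.064, for the integrated stress response 0.063 and for proneural genes 0.048. Correlation may therefore account for lost calls too. With a library left out 1 group holds 1 library, so a call lost in this way does not by itself show that a list rests on that library, and the median is given beside it. Over the 906 measured genes of all lists, 0 passed the edgeR threshold over all genes tested, 112 had an unadjusted p under 0.05 and 16 passed in DESeq2.

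Matrix glycoproteins and proteoglycans, the secreted scaffold around cells other than collagens, shifted upwards in COL8A1 cells. Of 40 measured members 32 were higher and 8 lower, with a median log2 fold change of 0.14 (camera adjusted p = 0.00305, and 0.845 with an estimated correlation). In edgeR 3 members, all higher, passed adjusted over the list alone, and the same number passed in DESeq2. They were POSTN (periostin; log2 fold change 0.68, SE 0.089), TGFBI (0.43, SE 0.059) and NID1 (nidogen, of basement membranes; 0.36, SE 0.060). POSTN was at 76.7 ± 6.2 CPM in NC and 123 ± 3.67 CPM in COL8A1 cells (n = 2), and TGFBI at 219.8 ± 3.97 and 296 ± 6.46 CPM. LTBP1, which binds latent TGF-beta, had a log2 fold change of 0.31 (SE 0.079) and passed in neither. The median deviation of the list from the gene means was −0.09 and −0.05 in NC replicates 1 and 2 and 0.16 and 0.02 in COL8A1 replicates 1 and 2 on the log2 scale. The call was lost without NC replicate 2 (camera adjusted p = 0.101, median 0.22) and without COL8A1 replicate 1 (0.0527, median 0.10). Markers of fibroblasts and pericytes, of which 2 are also in the matrix list, had 9 of 10 members higher (median 0.27, camera adjusted p = 0.0527, and 0.845 with an estimated correlation), with median deviations of −0.17 and −0.18 in NC replicates 1 and 2 and 0.21 and 0.15 in COL8A1 replicates 1 and 2. They were called without genes that differed over 2-fold within a group (camera adjusted p = 0.0203), a filter that can favour calls.

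Interferon response genes shifted downwards. Of 49 measured members 38 were lower and 11 higher, with a median log2 fold change of −0.17 (camera adjusted p = 0.000648, and 0.845 with an estimated correlation). In edgeR 0 members passed adjusted over the list alone, 7 were lower at an unadjusted p under 0.05, and 1, IFI44, passed in DESeq2 (adjusted p = 0.0193). The smallest edgeR p-values were those of the interferon-induced genes IFI44 (log2 fold change −0.63, SE 0.116; 25.4 ± 1.41 against 16.4 ± 0.95 CPM, n = 2), OAS3 (−0.42, SE 0.097), GBP2 (−0.54, SE 0.135) and OAS2 (−0.73, SE 0.208). The median deviation of the list from the gene means was 0.07 and 0.16 in NC replicates 1 and 2 and −0.003 and −0.16 in COL8A1 replicates 1 and 2 on the log2 scale. The call was lost without NC replicate 2 (camera adjusted p = 0.101, median −0.15) and without COL8A1 replicate 2 (0.0975, median −0.10).

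Genes of the integrated stress response, which ATF4 drives when amino acids are short or proteins misfold, also shifted downwards, with 26 of 33 members lower and a median of −0.15 (camera adjusted p = 0.00305, and 0.845 with an estimated correlation). ATF3, a stress-induced transcription factor, was at 12.8 ± 0.90 CPM in NC and 6.06 ± 2.07 CPM in COL8A1 cells (log2 fold change −1.08, SE 0.277, n = 2). GARS1, a tRNA ligase, and SLC7A11, the cystine transporter, had log2 fold changes of −0.29 (SE 0.088) and −0.27 (SE 0.088), while GDF15, a secreted stress factor, had one of 0.44 (SE 0.123). In edgeR 0 members passed adjusted over the list alone, 6 had an unadjusted p under 0.05 and 0 passed in DESeq2. The median deviations were 0.03 and 0.12 in NC replicates 1 and 2 and −0.03 and −0.05 in COL8A1 replicates 1 and 2. The call was lost without NC replicate 2 (camera adjusted p = 0.254), where 21 of 33 members were lower with a median of −0.14.

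Heat shock genes shifted downwards as well, with 17 of 20 members lower and a median of −0.14 (camera adjusted p = 0.0127, and 0.845 with an estimated correlation). The Hsp70 genes HSPA1B and HSPA1A, whose reads may be shared, had log2 fold changes of −0.20 (SE 0.059) and −0.19 (SE 0.068). The co-chaperones FKBP4 and STIP1 had log2 fold changes of −0.23 (SE 0.065) and −0.22 (SE 0.072). In edgeR 0 members passed adjusted over the list alone, 4 were lower at an unadjusted p under 0.05 and 0 passed in DESeq2. The median deviation of the list was 0.09 and 0.06 in NC replicates 1 and 2 and −0.12 and 0.001 in COL8A1 replicates 1 and 2. The call was lost without a low-count filter (camera adjusted p = 0.0687, median −0.15), without NC replicate 1 (0.144, median −0.11), without NC replicate 2 (0.161, median −0.16) and without COL8A1 replicate 1 (0.437, median −0.08).

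Ribosomal protein genes had 42 of 52 members lower, with a median of −0.09 (camera adjusted p = 0.0127, and 0.845 with an estimated correlation). RPL11 (log2 fold change −0.29, SE 0.089), RPL35 (−0.23, SE 0.067) and RPS18 (−0.15, SE 0.052) were lower and RPL32 was higher (0.33, SE 0.074). In edgeR 0 members passed adjusted over the list alone, 7 had an unadjusted p under 0.05 and 0 passed in DESeq2. The median deviations were 0.03 and 0.06 in the NC libraries and −0.08 and −0.01 in COL8A1 replicates 1 and 2. The call was lost without a low-count filter (camera adjusted p = 0.0689, median −0.10), without NC replicate 1 (0.0536, median −0.11), without NC replicate 2 (0.254, median −0.08) and without COL8A1 replicate 1 (0.439, median −0.05).

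Genes of the proneural glioma subtype had 14 of 16 measured members higher, with a median of 0.25 (camera adjusted p = 0.0127, and 0.845 with an estimated correlation). SOX9 and SOX4, transcription factors of neural and glial precursors, had log2 fold changes of 0.24 (SE 0.067) and 0.17 (SE 0.070), and the adhesion molecule NCAM1 one of 0.37 (SE 0.159). TUBB3, a neuronal tubulin, went the other way (−0.30, SE 0.130). In edgeR 0 members passed adjusted over the list alone, 1 had an unadjusted p under 0.05 and 0 passed in DESeq2. The median deviations were −0.10 and −0.08 in the NC libraries and 0.16 and −0.009 in COL8A1 replicates 1 and 2. The call was lost without a low-count filter (camera adjusted p = 0.0821, median 0.24), without NC replicate 1 (0.144, median 0.19), without NC replicate 2 (0.161, median 0.24) and without COL8A1 replicate 1 (0.229, median 0.11). Markers of astrocytes had 9 of 13 members higher (median 0.24, camera adjusted p = 0.0527, and 0.845 with an estimated correlation), and were called with a filter of 1 CPM (0.00254) and without genes that differed over 2-fold within a group (0.0203).

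**Figure D3:**
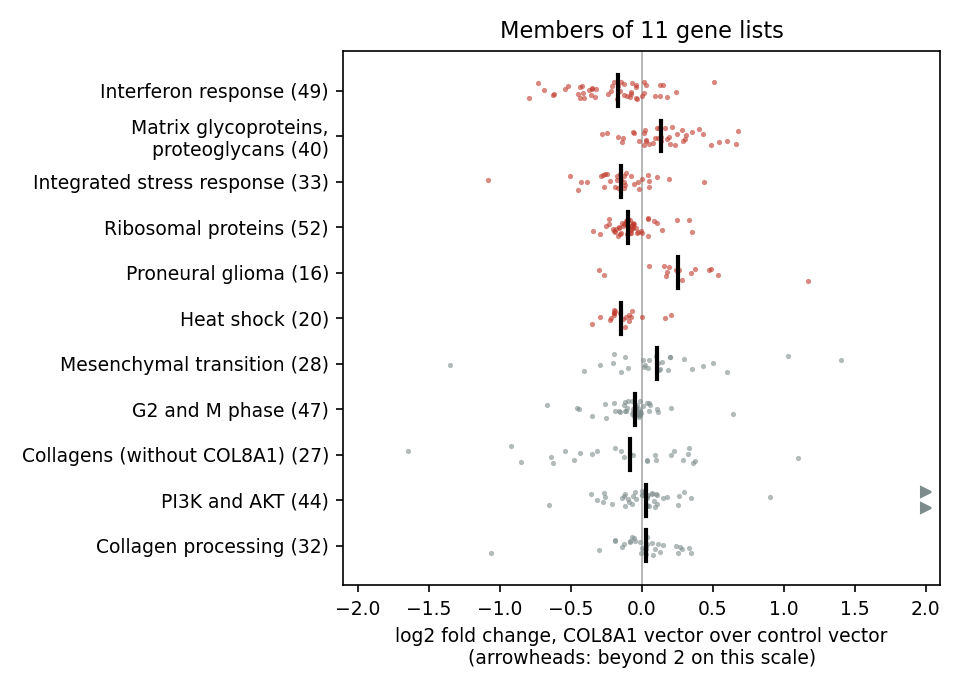
Log2 fold changes of COL8A1 over NC cells (horizontal axis) for the members of 11 gene lists (rows, with the number of measured members). Each point is a gene, black bars are medians, and red marks the 6 lists that camera called with the preset correlation. The medians ran from −0.17 for interferon response genes to 0.25 for proneural genes, and 2 members of the PI3K and AKT list lay beyond 2.

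The collagens other than COL8A1 went both ways and were not called (12 higher and 15 lower of 27, median −0.08, camera adjusted p = 0.445). Of the 27, 10 had an unadjusted edgeR p under 0.05 (6 higher, 4 lower), against 1033 of all 17030 genes tested. In edgeR 2 passed adjusted over the list alone, COL1A2 of collagen I, which was higher (log2 fold change 0.36, SE 0.059; 297.7 ± 3.25 against 383 ± 13.3 CPM, n = 2), and COL6A2 of collagen VI, which was lower (−0.64, SE 0.107; 25.1 ± 1.03 against 16.1 ± 0.036 CPM, n = 2). Both passed in DESeq2. COL5A1 (−0.85, SE 0.190) and COL4A6 (−0.48, SE 0.113) passed in neither. Genes of collagen processing had 19 of 32 members higher (median 0.03, camera adjusted p = 0.965). Their smallest edgeR p-values were those of PCOLCE2 (log2 fold change −1.06, SE 0.351, at 1.47 and 0.70 CPM), TLL1 (−0.30, SE 0.115), LOXL2 (−0.19, SE 0.089) and CRTAP (0.11, SE 0.054), and 0 passed adjusted over the list alone, 1 at an unadjusted p under 0.05 and 0 in DESeq2.

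The collagen receptors did not differ beyond the replicate spread in edgeR or DESeq2. The log2 fold changes were −0.08 (SE 0.081) for ITGB1, −0.03 (SE 0.064) for DDR2, 0.01 (SE 0.100) for DDR1, −0.15 (SE 0.426) for ITGA2 and −0.31 (SE 0.534) for ITGA1, which had 14 to 28 counts per library. Leaving out COL8A1 replicate 1 turned the sign of all 5.

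Mesenchymal transition genes had 20 of 28 members higher and were not called (median 0.11, camera adjusted p = 0.0844). TGFBI passed adjusted over the list alone in edgeR and passed in DESeq2. THY1 (log2 fold change 0.36, SE 0.069), the cadherin CDH11 (0.51, SE 0.124) and the integrin chain ITGB3 (1.03, SE 0.257, at 1.57 and 3.22 CPM) passed in neither. PI3K and AKT genes had 27 of 44 members higher (median 0.03, camera adjusted p = 0.752). TSC1 had a log2 fold change of 0.30 (SE 0.108). PIK3R2 had 37, 75, 4187 and 46 counts and BCL2L11 182, 394, 2027 and 461 in NC replicates 1 and 2 and COL8A1 replicates 1 and 2, with log2 fold changes of 5.27 (SE 2.001) and 2.19 (SE 0.731). Without COL8A1 replicate 1 these were −0.053 and 0.91. An overlapping gene (ENSG00000268173, named after its values were seen) had 3159, 3557, 4 and 2975 counts, so that its sum with PIK3R2 was 3196, 3632, 4191 and 3021. In edgeR 0 members passed adjusted over the list alone, 4 had an unadjusted p under 0.05 and 1 passed in DESeq2.

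Genes of the G2 and M phases had 38 of 47 members lower and were not called (median −0.04, camera adjusted p = 0.133). CDC25B, a mitotic phosphatase, had a log2 fold change of 0.20 (SE 0.055), and the mitotic genes AURKB, CKAP2L and TPX2 had values of −0.26 (SE 0.096), −0.25 (SE 0.106) and −0.16 (SE 0.066). In edgeR 0 passed adjusted over the list alone, 2 had an unadjusted p under 0.05 and 0 passed in DESeq2. With 1 library left out the median ran from −0.10 without COL8A1 replicate 2 (8 higher, 39 lower) to −0.014 without COL8A1 replicate 1 (22 higher, 25 lower). The median of the YAP and TEAD targets was −0.16 and 0.03 in the same 2 fits.

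The other lists were not called in the main setting either. Among signalling and stress lists the camera adjusted p was 0.175 for mitochondrially encoded genes, 0.392 for TGF-beta response and for YAP and TEAD targets, 0.537 for p53 targets and senescence, 0.617 for NF-kB inflammation, 0.675 for immediate early genes, for hypoxia and glycolysis and for nuclear-encoded oxidative phosphorylation, 0.764 for metallothioneins and oxidative stress and 0.965 for endoplasmic reticulum stress. It was 0.151 for replication-dependent histones (0.0203 without genes that differed over 2-fold within a group, 0.974 with a filter of 1 CPM, 0.845 with an estimated correlation). Further values were 0.2 for antigen presentation, 0.285 for secreted angiogenic factors, 0.515 for G1, S phase and replication, 0.665 for cholesterol synthesis, 0.752 for integrins and focal adhesion, 0.874 for matrix proteases and their inhibitors and 0.965 for the mesenchymal glioma subtype. Markers of endothelial cells (camera adjusted p = 0.38), oligodendrocytes (0.517), neurons (0.7), immune cells (0.756) and epithelial cells (0.965) had 3 to 9 measured members each. The median, the mean and the camera direction differed in sign for cholesterol synthesis, p53 targets, metallothioneins, matrix proteases and epithelial markers.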

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

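Robust dispersion shrinkage, sums over overlapping genes, lists without genes that differed over 2-fold within a group and lists without a length trend were chosen after seeing the data; the other settings were not. The count of 2 changed genes was the same with other scaling factors, library size alone, COL8A1 left out before scaling, a filter of 1 CPM, limma-voom, both fold thresholds and sums over overlapping genes. It was 17 without a low-count filter (11 higher, 6 lower), 180 in DESeq2 (103 higher, 77 lower) and 14 with robust shrinkage (8 higher, 6 lower), and 0 to 3 with 1 library left out; the cause was not tested. The log2 fold change of COL8A1 was positive in all settings run and passed the threshold without a filter (5.44), in DESeq2 (5.45) and without COL8A1 replicate 2 (5.77); it ran from 5.04 to 5.77 with 1 library left out. Of the lists, 3 were called without a filter, 0 with an estimated correlation, 0 by fry, 0 to 7 with 1 library left out, 7 with a filter of 1 CPM (astrocyte markers gained), 9 without genes that differed within a group (astrocyte markers, fibroblast and pericyte markers and replication-dependent histones gained) and 6 without the length trend. The sign turned without COL8A1 replicate 1 for 6 named genes, and without NC replicate 2 for DDR1 and ITGA2. With 1 library left out their log2 fold changes ran from −0.109 to 0.122 for DDR1, −0.62 to 0.426 for ITGA2, −0.074 to 0.009 for DDR2, −0.826 to 0.083 for ITGA1, −0.185 to 0.011 for ITGB1 and −0.053 to 6.248 for PIK3R2. Over the other named genes and settings, 598 values kept their sign and side of the threshold, 11 passed it and 6 no longer did.

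With the replicate number as a block, 1 gene (ZNF664) and 6 lists were called. Same-numbered libraries did not deviate together (rank correlation −0.051 across genes, which are not independent replicates), so no shared batch was seen over all genes. The split by replicate number gave 7 edgeR calls, against 2 for the vectors and 3 for the crosswise split. At an unadjusted edgeR p under 0.05 it gave the fewest genes, 505 against 1033 and 656. A batch that acts on few genes is not excluded, and the labels do not say what a shared number means. With 2 libraries per group and 2 residual degrees of freedom, edgeR recovered 56.7% of 2-fold changes simulated at the fitted dispersions (100% at 0.01 in all genes, below the fitted common 0.0508). A 2-fold difference in a gene that missed the threshold is thus not excluded. Larger ones are not excluded either: COL8A1 at 43.7-fold, ZNF672 at 5.8-fold and MAFG at 3.49-fold missed it in the real data. The simulation changed many genes at once, which eases the adjusted threshold, and did not model separate count levels. Its recovery may therefore not carry over to these data.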

Other observations

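The genes of the next paragraph, the example SKP1 with its neighbour ENSG00000272772, and the tests of overlapping genes, of nearby genes, of genes without a position, of list medians with a library left out, of exon share over all switching genes, of how often the 2-against-2 switches part the groups and of the count of genes in other splits were chosen after the results were seen.

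None of the following genes passed in edgeR over all genes tested, and their DESeq2 adjusted p-values may be too small. In the simulation at the fitted dispersions, DESeq2 made 61 false calls beside 55, 65 and 66 true ones at 2-fold, 4-fold and 16-fold. It also called 91 genes in the split by replicate number and 121 in the crosswise split, which do not part the vectors. The cholesterol synthesis list had 16 of 24 members higher, but INSIG1, which holds back sterol synthesis, and HMGCS1, an early enzyme of the pathway, had log2 fold changes of −0.94 (SE 0.091) and −0.85 (SE 0.159) and passed adjusted over the list alone. In DESeq2 the adjusted p was 5.59e-11 for INSIG1 and 0.00193 for HMGCS1. The antigen presentation list had 14 of 24 members lower, with HLA-B at 283.7 ± 8.51 CPM in NC and 174 ± 10.6 CPM in COL8A1 cells (log2 fold change −0.70, SE 0.073, DESeq2 adjusted p = 4.19e-08, n = 2). Among the matrix proteases and inhibitors, MMP2 (gelatinase A) and its inhibitor TIMP2 had log2 fold changes of 0.65 (SE 0.137, DESeq2 adjusted p = 0.0137) and 0.72 (SE 0.118, DESeq2 adjusted p = 0.000501). Of the astrocyte markers, the glutamate transporter SLC1A3 was at 27.3 ± 0.019 CPM in NC and 56 ± 4.57 CPM in COL8A1 cells (log2 fold change 1.04, SE 0.105, DESeq2 adjusted p = 2.52e-10, n = 2), and passed adjusted over the list alone with GFAP (1.63, SE 0.346, at 0.62 and 1.94 CPM) and GJA1 (0.25, SE 0.060). Outside the lists, the chromatin protein HMGB2 had a log2 fold change of −0.64 (SE 0.058, DESeq2 adjusted p = 1.67e-09).

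The 247 genes with separate count levels outnumber the 19 to 68 drawn with the fitted dispersions. Against the vector as their cause, 22 of the 2-against-2 switches parted the groups and 25 the most frequent other split. For the 120 with an overlapping counted gene, the median gain of the overlapping genes was 0.1% of the loss. This argues against reads moving between overlapping genes as the cause for most of the 120. In 12 (10%) the overlapping genes gained 50% to 150% of the loss, as for SKP1 with ENSG00000272772, so such moves stay open for single genes. Summing same-strand genes ended 32 of 58 switches, which dilution by an abundant neighbour gives too. In 7 of the 58 the same-strand genes gained 50% to 150% of the loss. The other 127 overlap no counted gene in the annotation used here, and 100 of them have a counted gene within 10 kb; reads moving to such neighbours are excluded as the cause for most of the 100, since in 4% (95% binomial interval 1.1% to 9.9%) the neighbours gained 50% to 150% of the loss, while moves to genes without a position are excluded only as the cause for all 127 together (missing reads at least 1.26 times all counts on them in every library) and stay open gene by gene, as in 78 such a gene gained 50% or more of the loss. A long exon remains a candidate explanation: protein-coding genes above the median share of the transcript held by the longest exon switched more often (odds ratio 5.14, 95% interval 3.62 to 7.47, two-sided Fisher's exact p = 1.07e-26 across genes, which are not independent replicates), from 0.26% of genes with a share of 2.5% to 35.9% to 4.98% with a share of 80.2% or more. How a long exon would do so, and reads shared with paralogs or pseudogenes, were not tested.

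ZNF664 and RAB31 belong to the 22 switches that part the groups, and DESeq2 called all 22. Both follow largely from the definition, which asks for close replicates and a large gap, so neither tells causes apart. Their exon shares had a median of 71.9%, against 57.6% in genes that do not switch (permutation p = 0.0237, one-sided), so the same long-exon explanation may hold for them. The 3 splits of the libraries into 2 and 2 are too few for a share under 0.05; the real one gave 2 edgeR calls and the highest other 7, and all 3 gave at least 2, but in DESeq2 the real one gave 180 calls and the highest other 121, and at an unadjusted edgeR p under 0.05 the counts were 1033 and 656. An effect of the COL8A1 vector on ZNF664 and RAB31 stays open.

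For the shifts of the 6 lists, the 3 splits are again too few for a share under 0.05: 1 of them, the real one, called 6 lists and the highest other called 0. Against a trend with transcript length as the whole cause, all 6 lists were called after it was removed. Dependence on single libraries stays open: 0 of the 6 were called without NC replicate 2, 2 without COL8A1 replicate 1, 3 without NC replicate 1 and 5 without COL8A1 replicate 2, but these fits have 1 library in a group, and the 24 medians of the 6 lists with 1 library left out kept their sign, at 43% to 172% of the main median. The kept signs weigh little, since the lists were chosen for their shifts in the same libraries. Without COL8A1 replicate 1 the medians were 43% of the main one for proneural genes, 56% for heat shock and 57% for ribosomal protein genes. They were 70% for the matrix list, 105% for the integrated stress response and 160% for interferon response genes. An effect of the vector on these lists stays open, as does correlation between genes. The 0 lists called with an estimated correlation cannot decide this alone, since that setting rests on the 2 residual degrees of freedom. The estimates for the 6 lists ran from 0.048 to 0.322, above the preset 0.01, so the camera p-values with the preset may be too small.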
